A study of Mus musculus with 6 samples.

How the data were processed

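RNA was sequenced from mouse E14 embryonic stem cells in N2B27 medium with LIF and 2i, transfected with control siRNA or with siRNA against Ehmt2 (2 μl of a 40 μM stock) and collected 3 days later, per the labels' protocols. Each group has 3 libraries, numbered 1 to 3. The title of 1 Ehmt2 siRNA library misspells the target, and its genotype label gives Ehmt2. Libraries were made from polyA-enriched RNA with a stranded TruSeq kit and sequenced as read pairs, per the labels' protocols.

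The submitters' processing notes name FastQC, Trimmomatic 0.36, STAR, DESeq2 and the genome builds mm10 and GRCm38. The gene annotation, the read counter, its use of strand and the settings of each step are not given in the sources used here. The authors deposited 1 table for the series, with a row per gene symbol. Its first column of values is the signal of each gene as the mean over all 6 libraries of read counts divided by size factors, per the file headers, which use DESeq2's column names. The deposited log2 fold changes compare the siRNA groups, and the header does not say which group is the numerator. The sign was read as Ehmt2 siRNA over control siRNA because Ehmt2 itself is negative, so the level of Ehmt2 cannot check the labels independently. The deposited p-values are unadjusted, per the file headers. Values per library are not in the table, so the depth of each library is unknown, and no interval from read counts was made. Genes with a single read in all libraries take 6 distinct values, from which the size factors were recovered (0.845 to 1.25, mean 1.05 on the Ehmt2 siRNA side and 0.966 on the control side). Which factor belongs to which replicate is unknown.

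The design fixed before the data were examined planned, for a table of this kind, to use the deposited adjusted p. As the table has none, adjusted p-values were computed from the deposited p-values by the Benjamini-Hochberg method over all 20461 genes with a p-value, and an adjusted p below 0.05 passes. The standard error of each gene was taken as the size of the log2 fold change divided by the normal quantile of its p-value, which assumes a Wald test. Single-read genes of every size factor and both signs gave the same standard error of 4.08 under that assumption. The 95% intervals use these errors.

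The genes named in the text follow a rule fixed before the data were examined. It takes Ehmt2 and Ehmt1, the 10 largest rises and 10 largest falls among passing genes with a mean normalized count of at least 50, the 3 smallest p-values in each direction, and up to 4 members with the smallest p-values of each gene list with a mean of at least 10. Predicted genes without a proper symbol were not named, and some genes that the rule selects are not reported here. Other genes are said in the text to have been chosen after their values were seen.

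Gene lists and symbol families were also fixed beforehand, and 32 had at least 5 tested members. They cover H3K9 methylation and the Ehmt2 complex, H3K9 demethylases, DNA methylation, naive pluripotency, formative and primed epiblast, germline, 2-cell-like, imprinted, trophectoderm, primitive endoderm, mesoderm and definitive endoderm, neural and fibroblast feeder genes, nucleolar granular and fibrillar genes, p53 targets, interferon response, integrated stress and unfolded protein response, cholesterol biosynthesis, glycolysis and hypoxia, cell cycle, Polycomb, Hox, clustered protocadherin, olfactory and vomeronasal receptor, keratin, Rhox, Zfp, Mage and Xlr, histone, ribosomal protein, and heat shock genes. A family of mitochondrially encoded genes had no member in the table, and 21 listed symbols were absent from it. Lists overlap, with 12 genes shared by the germline and the Mage and Xlr lists, 4 by trophectoderm and keratins, and 3 each by trophectoderm and Rhox, by primitive endoderm and mesoderm, by DNA methylation and formative epiblast, and by the stress response and chaperone lists. Other overlaps hold 1 or 2 genes. For each list and direction a two-sided Fisher's exact test set the passing members against all tested genes, with Benjamini-Hochberg adjustment over 64 tests. The median log2 fold change of a list was placed among 10000 random lists drawn from 20 strata of mean expression.

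Coordinates and gene types come from the RefSeq annotation of GRCm38, to which 99.2% of symbols matched. GC content was that of the longest GENCODE M21 transcript of each symbol (97.2% of tested genes, 98.8% of passing genes). To remove the trend on GC content, a lowess curve (fraction 0.3) fitted on genes with a mean of at least 50 was subtracted, and p-values were recomputed with the same standard errors.

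The steps were tested on simulated data, with fold changes of 19896 genes drawn around 0 with their implied errors. Of these, 200 genes with a mean normalized count of at least 50 were changed by 1 on the log2 scale. Changes in genes with lower counts were not simulated. The errors drawn were those that the test assumes, which by itself keeps few unchanged genes passing without a GC trend. Without a GC trend 95% of the changed genes were recovered and 7 unchanged genes passed. With the GC trend of the table added, 93% were recovered and 78 unchanged genes passed (0.396%), and after removal of the trend 92% and 9.

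Alternatives were an adjusted p below 0.01, a log2 fold change of at least 1 in size, genes with a mean normalized count of at least 50 only, and, chosen after seeing the data, adjustment over the 16543 genes that the table lists in order of significance and removal of the GC trend. Work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.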

Results

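Gene expression was measured by RNA sequencing in E14 cells, a male mouse embryonic stem cell line kept in N2B27 medium with LIF and 2i inhibitors. Cells received either a control siRNA or an siRNA against Ehmt2, the H3K9 methyltransferase also known as G9a, and were collected 3 days later. Each group had 3 libraries. The values available are 1 comparison of the groups, in the authors' deposited table, which lists 25239 genes with a mean normalized count over all 6 libraries, a log2 fold change and a p-value. Of these genes, 4778 were at 0 in all libraries and 20461 carried a p-value. Values per library were not in the table, so read totals are unknown. Library size factors, recovered from genes with a single read, ranged from 0.845 to 1.25. The series title places the experiment in a study of the nucleolus and of the genomic domains that associate with it. The question addressed here is which transcripts change when Ehmt2 is reduced. All log2 fold changes below are Ehmt2 siRNA over control siRNA from the authors' deposited table, and 95% intervals are those that the deposited fold change and p-value imply.

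Ehmt2 (chromosome 17, 34898463 to 34914073, GRCm38) fell to 34.7% of its control level, with an interval of 29.4% to 41.0%. Its log2 fold change in the authors' deposited table was -1.53, and the p-value of the authors' DESeq2 comparison, 3.51e-36, gave a Benjamini-Hochberg adjusted p of 2.87e-33 when adjusted here over all tested genes. The table does not state which group is the numerator, and the direction used throughout was read from this fall. Ehmt1, which encodes the partner of Ehmt2 in the methyltransferase complex, had a log2 fold change of -0.05 with an interval of -0.22 to 0.11 and did not pass the test.

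Reduction of Ehmt2 was accompanied by strong rises of genes with low mean counts, led by Mage, Usp17l, Zscan4 and Khdc1 family members. Falls were smaller at the median over all passing genes and included Krt8, Krt18, Cebpb, Gata2, Gata4, Clu, Emilin3 and Inhbb. In all, 2103 of 20461 genes passed the test (Benjamini-Hochberg adjusted p below 0.05), of which 1116 rose and 987 fell. The median log2 fold change was 0.64 among genes that rose and -0.53 among genes that fell. With a log2 fold change of at least 1 in either direction also required, 429 genes rose and 155 fell. Genes annotated as long noncoding RNAs rose in 64 cases and fell in 9, against 1029 and 974 for protein-coding genes. These types were not compared at equal expression. Rises outnumbered falls among all genes with low mean counts (50 and 2 below 10, 179 and 56 from 10 to 50). The imbalance thus cannot be assigned to gene type. Among 1581 genes with a mean normalized count of 10000 or more, 73 rose and 59 fell, with median log2 fold changes of 0.24 and -0.23. Falls were slightly larger than rises at means of 500 to 1000 (median -0.55 against 0.49). The same held at 1000 to 5000 (-0.34 against 0.32) and 5000 to 10000 (-0.27 against 0.26).

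**Figure D1:**
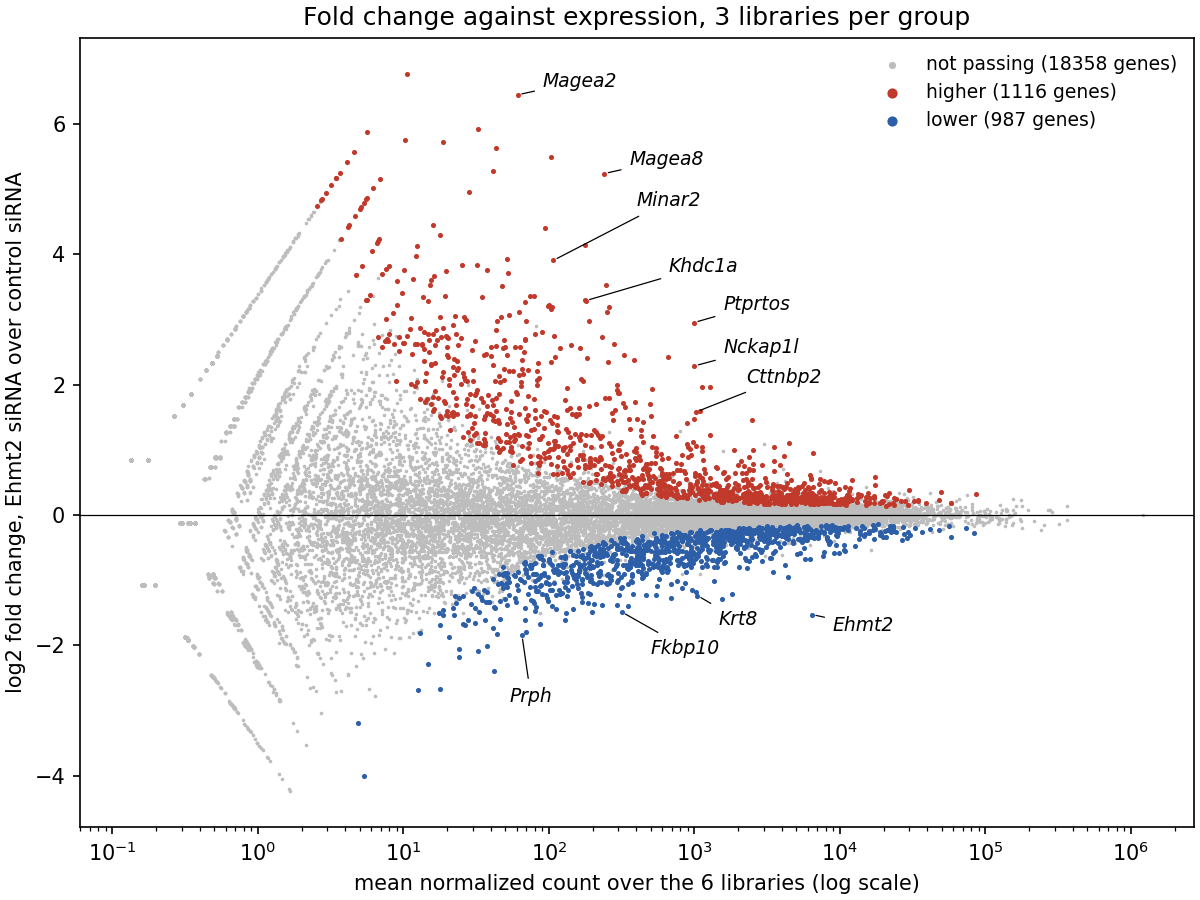
Log2 fold change of each tested gene (vertical axis, Ehmt2 siRNA over control siRNA) against its mean normalized count over 6 libraries (horizontal axis, log scale). Points are genes, coloured by whether they passed the test, with 1116 higher and 987 lower, and the largest rises belong to genes of low mean count.

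Among genes with a mean normalized count of at least 50, predicted genes and unnamed clones left out, the largest rises were those of Magea2 (log2 fold change 6.45), Magea8 (5.24) and Magea5 (4.14), which lie on the X chromosome between 154985775 and 155063151. Next came Usp17la (3.93), Minar2 (3.91), Usp17lb (3.71), Nlrp4c (3.52), Usp17le (3.36), Khdc1a (3.29) and Zscan4d (3.27). The interval of Magea2 ran from 4.94 to 7.96 and that of Magea8 from 4.66 to 5.82. Magea, Usp17l, Nlrp4, Khdc1 and Zscan4 genes have near-identical copies between which reads may be shared, so the level of any single copy is uncertain. The largest falls were those of Prph (-1.84), Inhbb (-1.79), Tmem125 (-1.67), Emilin3 (-1.62), Shisal2a (-1.60), Ehmt2 (-1.53), Padi4 (-1.51), Fkbp10 (-1.49), Cebpb (-1.48) and Fut2 (-1.47). The smallest p-values among genes that rose belonged to Ptprtos (2.95, interval 2.77 to 3.14), Nckap1l (2.29, 2.09 to 2.48) and Cttnbp2 (1.59, 1.42 to 1.75). Ptprtos is an antisense transcript of Ptprt, which was read after its value was seen and whose own log2 fold change of 1.45 did not pass the test (adjusted p 0.172). The library kit was stranded, but whether counting used strand is not given in the sources used here, so reads of this pair may be mixed. Among genes that fell, the smallest p-values belonged to Krt8 (-1.23, interval -1.41 to -1.06), Ehmt2 and Clu (-1.04, -1.22 to -0.85).

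**Figure D2:**
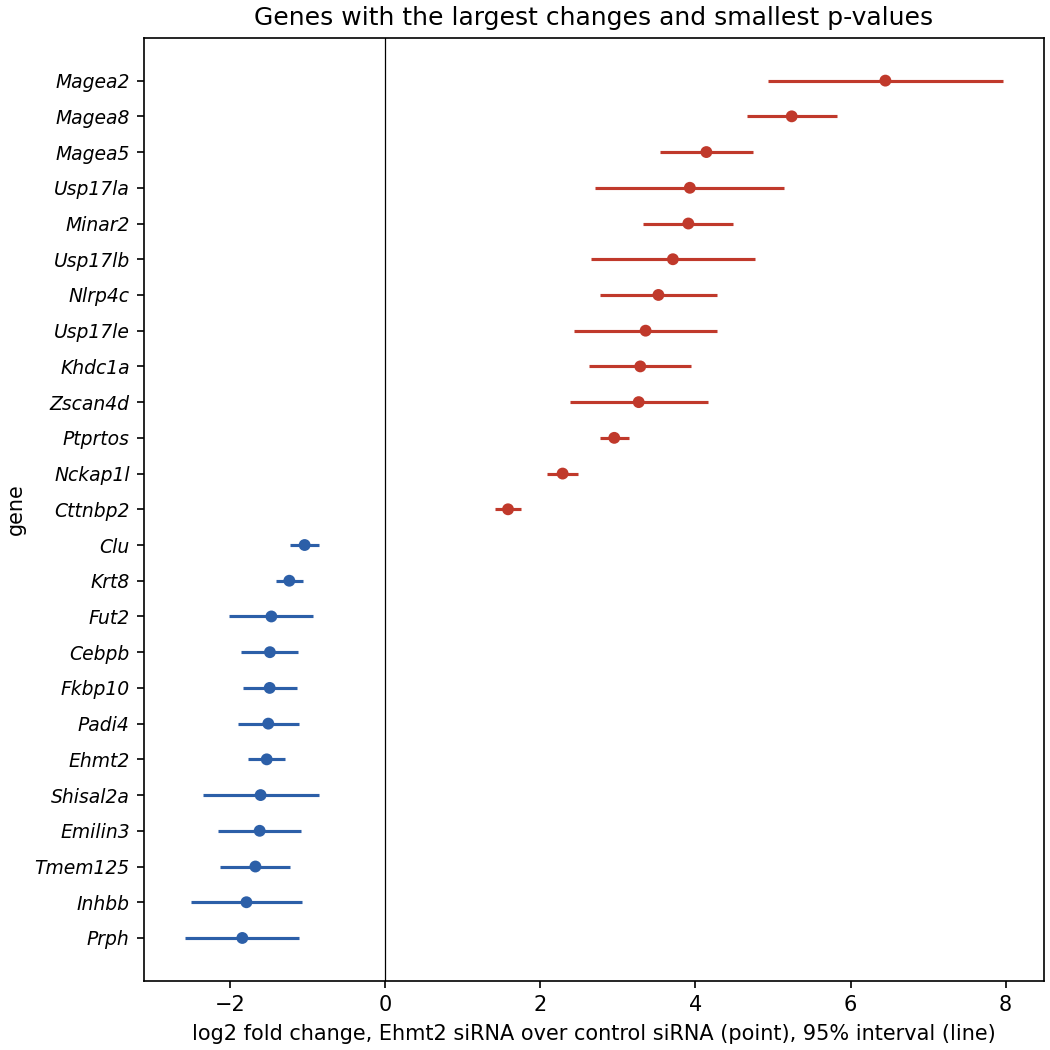
Log2 fold change (point) and implied 95% interval (line) of Ehmt2, of the genes with the largest rises and falls, and of those with the smallest p-values, each from the comparison of 3 Ehmt2 siRNA with 3 control siRNA libraries. Every interval lies away from 0, from Prph at -1.84 to Magea2 at 6.45.

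Genes of the 2-cell-like state, a rare state of stem cell cultures that shares transcripts with the 2-cell embryo, rose as a group. Of 40 members tested, 25 rose, none fell and 15 did not pass, and at an unadjusted p under 0.05 the authors' comparison gives 28 higher and 0 lower. By chance 2.18 would rise (two-sided Fisher's exact test, Benjamini-Hochberg adjusted over 64 list tests, p 2.37e-20). When p-values were adjusted over the list alone, 28 rose and 0 fell. The median log2 fold change of the list was 2.35, at percentile 100 of 10000 random lists matched on expression. Pramel6 rose by a log2 fold change of 2.46 (adjusted p 7.33e-42), beside Zscan4d, Usp17le and Usp17lb. All 5 Zscan4 genes tested in the cluster on chromosome 7 (10794241 to 11402318) rose, with log2 fold changes of 2.36 to 3.27, and all 5 Usp17l genes (chromosome 7, 103250086 to 104862667) rose by 2.57 to 3.93. Dux, read after its value was seen, had a mean normalized count of 2.85 and a log2 fold change of 1.62 that did not pass (adjusted p 0.625).

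Germline genes and X-linked gene families also rose. Of 70 germline genes tested, 22 rose, 2 fell and 46 did not pass, against 3.82 rises by chance (Fisher adjusted p 1.47e-10), and 25 rose and 5 fell when adjusted over the list alone. Magea4 rose by 2.43 and Tktl2 by 2.57 on the log2 scale, and among members chosen after their values were seen, Asz1 rose by 2.62 and Gtsf1 by 1.55. Of 28 Mage and Xlr genes, 16 rose and 0 fell (adjusted p 1.93e-12; 17 rose when adjusted over the list alone, and none fell at an unadjusted p under 0.05), with 12 members shared with the germline list. All 7 Magea genes tested rose. Of 24 Rhox genes, 7 rose and 0 fell (adjusted p 0.00229; 13 rose when adjusted over the list alone, and none fell at an unadjusted p under 0.05). Rhox5 rose by 1.04, and 5 of 8 Rhox2 copies on the X chromosome (37244992 to 37673277) rose, among them Rhox2h (3.53), Rhox2c (2.30) and Rhox2b (1.98). Reads of the Rhox2, Xlr and Magea copies may be shared.

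**Figure D3:**
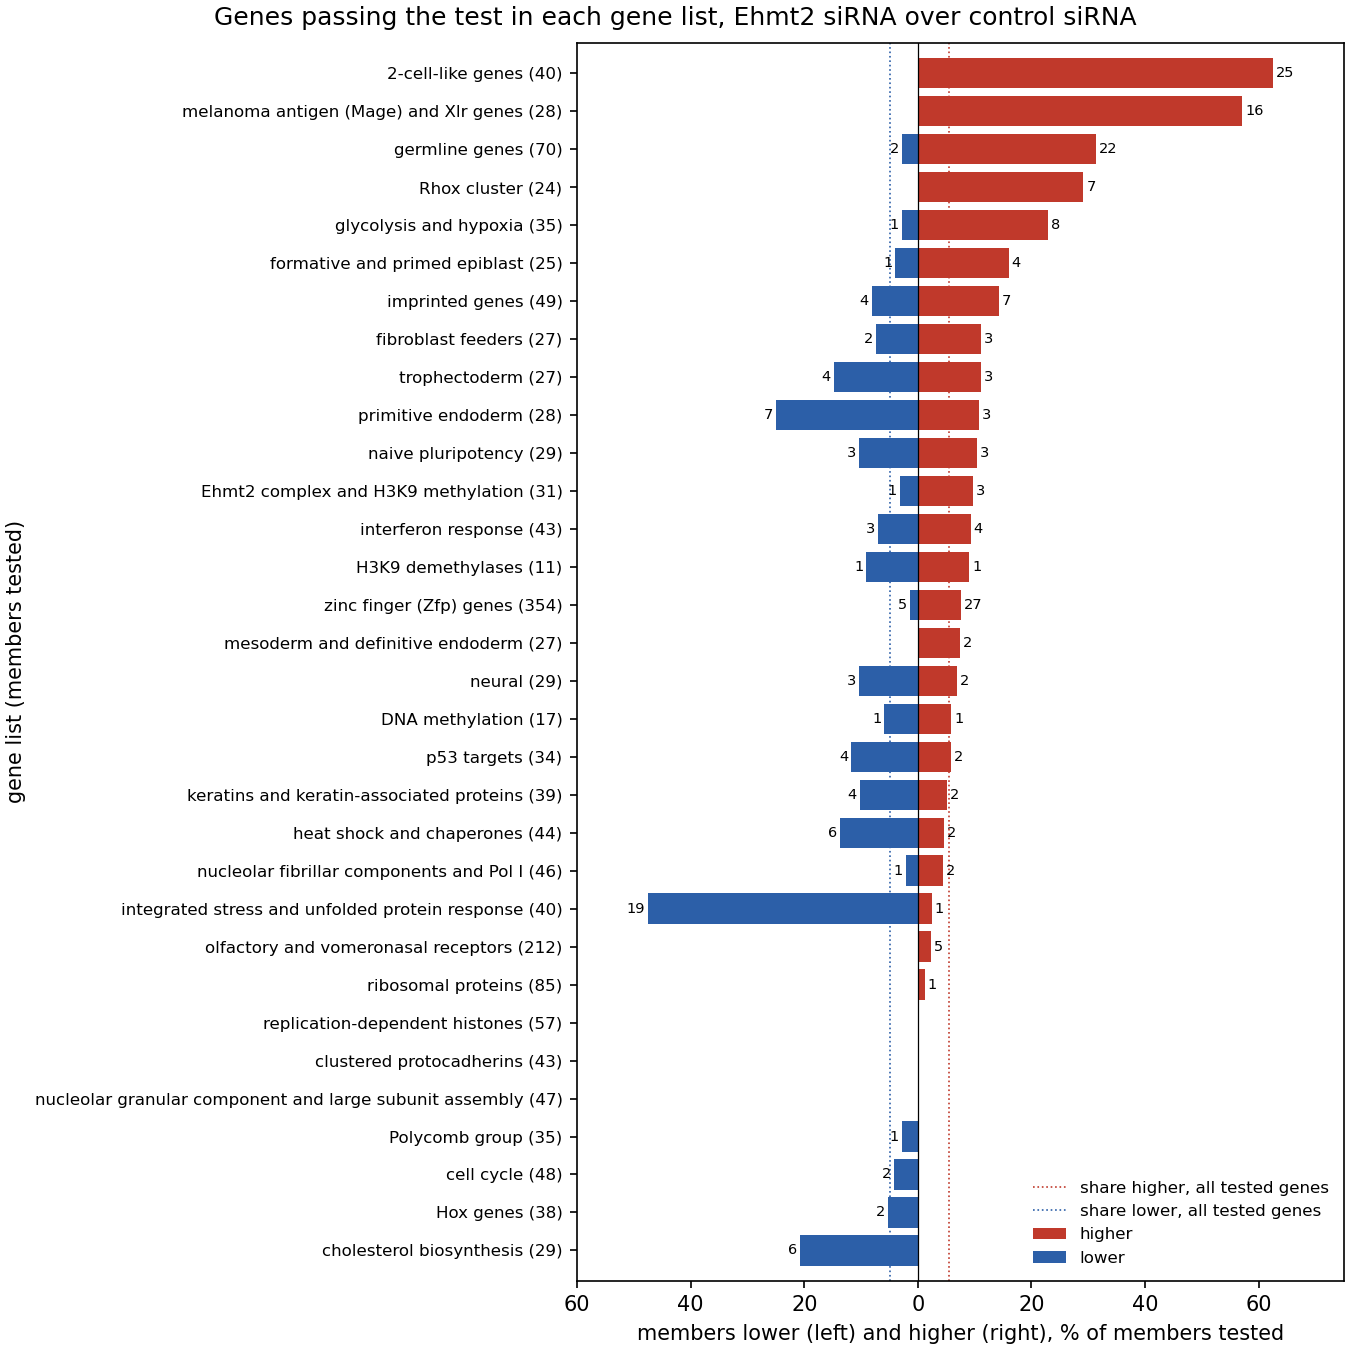
Share of the members of each gene list that rose (right, red) or fell (left, blue), in percent of members tested, with the number of genes at each bar and the number tested in brackets. Dotted lines mark the shares among all tested genes, with 25 of 40 2-cell-like and 16 of 28 Mage and Xlr genes higher, and 19 of 40 stress response genes lower.

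Genes of the integrated stress and unfolded protein response fell. Of 40 members, 19 fell, 1 rose and 20 did not pass, where 1.93 falls would be found by chance (Fisher adjusted p 1.31e-13), and 24 fell when adjusted over the list alone. Cebpb fell by 1.48, Chac1 by 0.80, Trib3 by 0.68 and Aars by 0.34 on the log2 scale. Chosen after their values were seen, Atf4 fell by 0.29, Atf3 by 1.02 and Ddit3 by 0.71, while Dnajb9 was the member that rose (0.26), though not after removal of the GC trend described below (log2 fold change 0.16, adjusted p 0.327). The median log2 fold change of the list was -0.29, at percentile 0 of the matched random lists.

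Metabolic genes changed by smaller amounts. Of 35 glycolysis and hypoxia genes, 8 rose and 1 fell (1.91 rises by chance, Fisher adjusted p 0.00384), and 12 rose when adjusted over the list alone. Bnip3 rose by 0.98, P4ha1 by 0.51 and Pgk1 by 0.36, while Eno2 fell by 0.75. Of 29 cholesterol biosynthesis genes, 6 fell and 0 rose (1.40 falls by chance, adjusted p 0.0145), 7 fell when adjusted over the list alone, and none rose at an unadjusted p under 0.05. Scd1 fell by 0.26, Tm7sf2 by 0.26 and Srebf2 by 0.22. The fall of Srebf2 did not pass once the GC trend was removed (log2 fold change -0.11, adjusted p 0.150). Over the genes listed in order of significance, the excess of cholesterol falls did not pass (Fisher adjusted p 0.0535). The excess of glycolysis rises did not pass when genes were called at an adjusted p below 0.01 (Fisher adjusted p 0.385).

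Naive pluripotency genes moved both ways by small amounts. Of 29 members, 3 rose and 3 fell against 1.58 and 1.40 by chance (Fisher adjusted p 0.417 and 0.390), and 4 rose and 3 fell when adjusted over the list alone. Tcl1 rose by 0.52 and Fbxo15 by 0.26, while Tet2 fell by 0.21 and Nr0b1 by 0.24, the latter not passing after removal of the GC trend (log2 fold change -0.16, adjusted p 0.119). Read after their values were seen, Pou5f1 (-0.11), Sox2 (0.15) and Nanog (0.15) did not pass. Among 25 formative and primed epiblast genes 4 rose and 1 fell, as many as when adjusted over the list alone. Grhl2 (1.21), Lefty1 (1.09) and Lef1 (1.01) rose and Fgf15 (-1.32) fell. The excess of rises did not pass (Fisher adjusted p 0.186). The median of that list, 0.09, lay at percentile 98.28 of the matched random lists (99.52 after removal of the GC trend).

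Marker genes of other lineages moved both ways within most lists. Of 28 genes on the primitive endoderm list 7 fell and 3 rose (1.35 falls by chance, Fisher adjusted p 0.00264). When adjusted over the list alone, 8 fell and 4 rose. Amn (-2.29), Sparc (-0.33) and Gata4 (to 49.9% of its control level) fell. Sox21, a list member not particular to this lineage, rose (0.85). That excess of falls did not pass after removal of the GC trend (adjusted p 0.115). In the trophectoderm list 4 of 27 fell and 3 rose (5 and 3 adjusted over the list alone), and its median of -0.32 lay at percentile 0.03 of the matched random lists, with falls of Krt8, Krt18 (-1.22) and Gata2 (to 49.8% of its control level) beside the rise of Rhox5, and Cdx2, named after its value was seen, rose by 1.31. The neural list had 2 rises and 3 falls among 29 genes (3 and 4 adjusted over the list alone), among them Neurod1 (1.42), Snap25 (2.69) and Ncam1 (-0.80), and Nes (-0.27), which did not pass after removal of the GC trend (log2 fold change -0.18, adjusted p 0.140). Mesoderm and definitive endoderm genes rose in 2 of 27 cases and fell in 0 (3 falls at an unadjusted p under 0.05), and none passed when adjusted over the list alone. These were Wnt3 (1.68) and Pdgfra (0.64), the latter at 0.62 and just short of passing after removal of the GC trend (adjusted p 0.0459 before and 0.0652 after). Genes of fibroblast feeders rose in 3 of 27 cases and fell in 2 (3 and 4 adjusted over the list alone), with Col1a2 at 2.43, Col5a2 at 1.23, Ccn2 at 0.97 and Timp1 at -0.32, although the median of that list was negative (-0.30).

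Chromatin regulators changed little. Of 31 genes of H3K9 methylation and the Ehmt2 complex, Zfp518a (0.58), Resf1 (0.32) and Atf7ip2 (0.28) rose and Tasor2 (-0.40) fell, 3 and 1 also when adjusted over the list alone. Among 11 H3K9 demethylases Kdm3a rose (0.43) and Kdm4a fell (-0.19), and among 17 DNA methylation genes Zbtb33 rose (0.35) and Tet2 fell, each 1 and 1 adjusted over the list alone. After removal of the GC trend Atf7ip2, Kdm4a and Zbtb33 stood at 0.19, -0.13 and 0.24 and did not pass (adjusted p 0.108, 0.166 and 0.158). Of 35 Polycomb genes 1 fell, both overall and adjusted over the list alone, and 0 rose against 2 at an unadjusted p under 0.05, with Bmi1 at 0.19 and Pcgf3 at 0.20, neither passing. Imprinted genes rose in 7 of 49 cases and fell in 4 (9 and 6 adjusted over the list alone), with Usp29 (1.33) and Sfmbt2 (0.77) higher and Slc22a18 (-0.81) and Phlda2 (-0.79) lower.

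Other large gene families showed no excess of rises or falls that passed the list test. Yet the Zfp median of 0.05 lay at percentile 100 of the matched random lists (98.85 after removal of the GC trend). The Hox median of -0.27 lay at percentile 0.83 (1.3 after), and medians of the other families here between 5.86 and 95.27. Of 354 Zfp genes 27 rose and 5 fell (25 and 5 adjusted over the list alone, and 13 and 6 of 352 after removal of the GC trend), with Zfp558 (0.72), Zfp770 (0.54) and Zfp638 (0.30) higher and Zfp869 (-0.67) lower. The number of falling Zfp genes was below the 17.1 given by chance (Fisher adjusted p 0.00699), but not after removal of the GC trend (adjusted p 0.274). Among 212 olfactory and vomeronasal receptor genes 5 rose and 0 fell (2 and 0 adjusted over the list alone, and no fall at an unadjusted p under 0.05), among them Olfr701 (2.08) and Olfr1494 (1.79). The lack of falls among them (10.2 by chance, Fisher adjusted p 7.83e-04) was not found among the 16543 genes that the table lists in order of significance (adjusted p 0.611). Too few receptor genes reach a mean normalized count of 50 to be tested there. Among all 5315 genes with a mean below 10, only 2 fell and 50 rose. The share of falls over all genes is thus no fair expectation for receptors, and their lack of falls decides little. Of 38 Hox genes Hoxc6 (-0.55) and Hoxd13 (-1.09) fell, none of them when adjusted over the list alone, and 0 rose, also at an unadjusted p under 0.05. After removal of the GC trend Hoxc6 stood at -0.50 and was just short of passing (adjusted p 0.0274 before and 0.0584 after). Hoxc10 (-0.63, adjusted p 0.0547) passed among genes with a mean normalized count of at least 50 (0.0402) and among those listed in order of significance (0.0443). None of 43 clustered protocadherin genes passed, whether adjusted over all genes or adjusted over the list alone, where 2 were higher and 0 lower at an unadjusted p under 0.05 in the authors' DESeq2 comparison. After removal of the GC trend Pcdhgc3 passed (log2 fold change 0.22, or 0.30 after removal). Keratin genes fell in 4 of 39 cases and rose in 2, the same counts as adjusted over the list alone, with Krt17 at -1.21 and Krt42 at 0.47. The excess of keratin falls (adjusted p 0.326) passed among genes with a mean normalized count of at least 50 (0.0356).

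Few nucleolar, ribosomal protein and cell cycle genes passed the test. Yet the ribosomal protein median of -0.03 lay at percentile 0.48 of the matched random lists (2.995 after removal of the GC trend). The cell cycle median of 0.06 lay at percentile 98 (97.79 after). None of 47 genes of the nucleolar granular component and large subunit assembly passed, overall or adjusted over the list alone, where the authors' DESeq2 comparison gives 1 higher and 2 lower at an unadjusted p under 0.05. In that list the smallest adjusted p, 0.0553, was that of Noc2l (-0.14), which passed among genes with a mean normalized count of at least 50 (adjusted p 0.0406) and among those listed in order of significance (0.0448). Npm1, read after its value was seen, stood at 0.08 (interval -0.06 to 0.21). Of 46 genes of the fibrillar components and Pol I, Taf1d (0.21) and Wdr75 (0.15) rose and Rrp9 (-0.26) fell, 2 and 1 adjusted over the list alone, and after removal of the GC trend these 3 stood at 0.11, 0.10 and -0.14 in that order and did not pass (adjusted p 0.287, 0.311 and 0.403). Of 85 ribosomal protein genes 1 rose, Rpl39l (0.83), also adjusted over the list alone, and 0 fell against 2 at an unadjusted p under 0.05. None of 57 replication-dependent histone genes passed at any of these thresholds, the unadjusted p under 0.05 included. Their transcripts mostly lack a polyA tail and the libraries were polyA-enriched, so this list cannot show whether they changed. Of 48 cell cycle genes Ccnd2 (-0.91) and Ccnd3 (-0.23) fell, 2 also adjusted over the list alone, and 0 rose against 1 at an unadjusted p under 0.05. The fall of Ccnd3 did not pass after removal of the GC trend (log2 fold change -0.13, adjusted p 0.314). No mitochondrially encoded gene was in the table.

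Remaining stress lists were mixed. Heat shock and chaperone genes fell in 6 of 44 cases and rose in 2 (6 and 3 adjusted over the list alone), with Hspb7 (-0.91), Dnajb13 (-0.79) and Hspa9 (-0.27) lower, although the median of that list was positive (0.06). Among 34 p53 targets 4 fell and 2 rose (6 and 2 adjusted over the list alone, 8 and 2 at an unadjusted p under 0.05). The excess of falls did not pass (Fisher adjusted p 0.268). The p53 median of -0.04 lay at percentile 8.98 of the matched random lists (0.47 after removal of the GC trend). Gdf15 (-0.79) and Perp (-0.56) were lower and Rprm (1.19) higher. Sesn2 (-0.28) was lower except after removal of the GC trend (log2 fold change -0.17, adjusted p 0.209). Interferon response genes rose in 4 of 43 cases and fell in 3 (4 and 5 adjusted over the list alone), with Ifi27 (1.87) and Ifih1 (0.93) higher and H2-K1 (-0.76) and Bst2 (-0.69) lower. Of all 64 list tests, 10 passed, including the shortage of receptor falls, which decides little. Genes within a list are not independent replicates.

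Fold changes followed the GC content of transcripts. Across 12728 genes with a mean normalized count of at least 50, Spearman's rho between log2 fold change and GC content was -0.42, a correlation across genes, which are not independent replicates. When these genes were split into 10 equal groups by GC content, 190 rose and 7 fell in the lowest group, and 12 rose and 233 fell in the highest. The medians of these groups were 0.10 and -0.13 on the log2 scale. Among 10929 genes that did not pass the test rho was -0.37. With a smooth trend on GC content subtracted, 1594 of 19896 genes passed, 891 higher and 703 lower, of which 822 and 638 also passed without it.

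**Figure D4:**
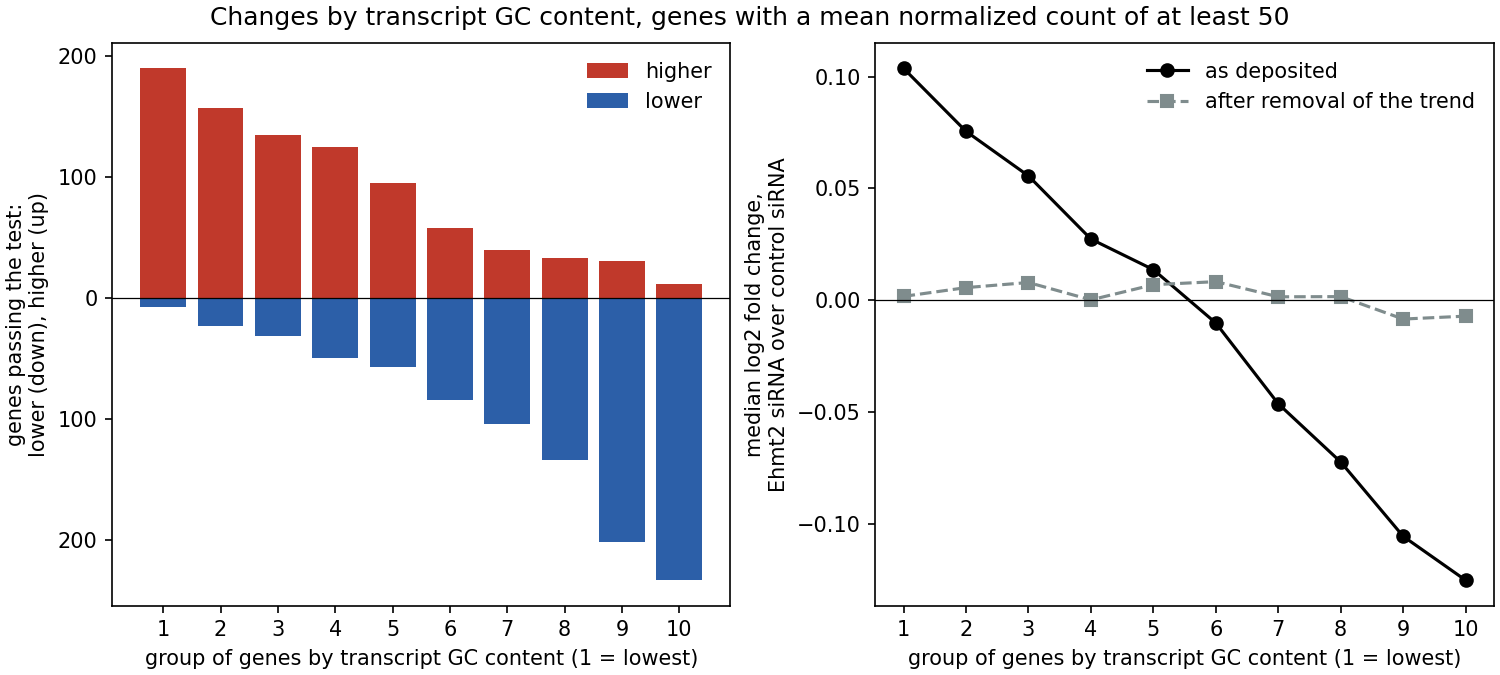
Left, genes that rose (red, upward) or fell (blue, downward) in each of 10 equal groups of 12728 genes ordered by transcript GC content. Right, the median log2 fold change of each group, Ehmt2 siRNA over control siRNA, which runs from 0.10 to -0.13 as deposited and stays near 0 after removal of the trend.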

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

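Adjustment over the genes listed in order of significance and removal of the GC trend were chosen after seeing the data, and the other alternatives before. Ehmt2 kept its fall and passed under every alternative run (log2 fold change -1.41 after removal of the GC trend, -1.53 otherwise). With an adjusted p below 0.01, 1327 genes passed (726 higher, 601 lower), and with a log2 fold change of at least 1 in size 584 (429 higher, 155 lower), both by construction. Among genes with a mean of at least 50, falls outnumbered rises (968 higher, 1032 lower). The alternatives other than the stricter p and size thresholds gave 1594 to 2234 genes. Rises of 2-cell-like, germline, Mage and Xlr, and Rhox genes passed under every alternative run. The falls of stress response genes failed only with a log2 fold change of at least 1 (adjusted p 0.214), and otherwise ranged from 9.93e-14 to 6.59e-10. Under that size threshold the shortage of falls among Zfp genes (0.563) and olfactory and vomeronasal receptors (1) did not pass, and with 0 members past it the cholesterol and glycolysis lists turned from more to fewer changes than chance (both 1). At an adjusted p below 0.01, falls of primitive endoderm genes (0.0552) and rises of glycolysis genes (0.385) did not pass. Over the genes listed by significance, the falls of cholesterol genes (0.0535) and the shortage of receptor falls (0.611) did not pass. Without the GC trend, the falls of primitive endoderm genes (0.115) and the shortage of Zfp falls (0.274) did not pass. Other list tests newly passed, namely falls of keratins with the size threshold (0.00271), with a mean of at least 50 (0.0356) and over the genes listed by significance (0.0486), falls of trophectoderm genes with the size threshold (0.0111), and the shortage of falls among ribosomal protein genes with a mean of at least 50 (0.0120) and over the listed genes (0.0451). Over all alternatives run, adjusted p ranged from 0.00166 to 0.115 for primitive endoderm, 8.84e-05 to 0.563 for Zfp genes, 0.00807 to 1 for olfactory and vomeronasal receptors, 0.00413 to 1 for cholesterol and 2.72e-06 to 1 for glycolysis. Beyond the size threshold, the cause was not tested. Of the genes chosen by the fixed rule none changed direction, 13 stopped passing and 1 passed newly without the GC trend, and 2 passed newly both with a mean of at least 50 and over the listed genes. With a mean of at least 50, olfactory and vomeronasal receptors had too few members to test. No paired analysis was possible because the table has no values per library. For the same reason other size factors, no low-count filter, a replicate block, leaving out each library, DESeq2 against edgeR, another pseudocount and an estimated correlation between genes (camera) were not run, and other splits of the samples could not be drawn. Depth limits what low genes can show, as the median implied standard error was 2.04 below a mean count of 10 and 0.0748 at 10000 or more.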

Other observations

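Chosen only after the result was seen were the tests of a whole-chromosome X shift and of Y loss, the repeat on genes with a single transcript, and the tests that use removal of the GC trend as an added alternative. Rises were concentrated on the X chromosome, where 107 of 795 tested genes rose (13.5%) and 7 fell, against 5.12% rising elsewhere (Fisher's exact test, Benjamini-Hochberg adjusted over chromosomes and directions, p 1.31e-16). Chromosome 1 also had an excess of rises (7.88% against 5.29% elsewhere, adjusted p 0.00211), as did the Y chromosome (4 of 12 genes, 0.0116), and both still passed after removal of the GC trend (0.0162 and 0.0124). Falls were in excess on chromosomes 4 (6.95%), 7 (6.90%), 11 (6.75%) and 15 (7.20%), and after removal of the GC trend on chromosome 15 (5.89% against 3.44% elsewhere, adjusted p 0.00754) but not on the others. On the Y chromosome, among genes read after their values were seen, Kdm5d (log2 fold change 2.35), Usp9y (2.23), Zfy1 (1.22) and Uba1y (0.73) rose, while Uty (0.18), Ddx3y (0.15) and Eif2s3y (0.06) did not pass. Predicted genes and unnamed clones rose in 116 cases and fell in 13, and were not compared with other genes at equal expression.

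Genes with a single read in all libraries numbered 855, of which 502 had that read on the Ehmt2 siRNA side and 353 on the control side. The Ehmt2 share was 58.7% (exact binomial 95% interval 55.3% to 62.0%, for counting error only) against 52.1% from the size factors (exact binomial p 1.08e-04). Rates per library gave an exact permutation p of 0.1, the smallest that 3 against 3 libraries allow.

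The trend of fold changes on GC content was weighed against a bias between libraries. After removal of the trend, 24 of 25 passing 2-cell-like members and 20 of 22 passing germline members still passed (at least 90.9%). The subtracted trend ran only from -0.163 to 0.196 on the log2 scale. Median rises of these members were 2.57 and 1.24 before removal and 2.47 and 1.19 after. Few of them could therefore have stopped passing, and the count by itself decides little. A trend of that size is too small to be the whole cause of those median rises. In the stress response list 14 genes fell after removal, 13 of them among the 19 before (Fisher p 4.12e-11), so the trend is not the whole cause there either, although the list median moved from -0.29 to -0.22. Within housekeeping lists rho was -0.382 (95% bootstrap interval -0.488 to -0.258, 258 genes), which argues against a trend confined to other genes. The slope on the GC content of 10 flanking genes was 1.10 times that on a transcript's own GC content (0.927 to 1.28, and 1.45, 0.867 to 2.48, over 1215 genes with a single annotated transcript), where a bias acting on a transcript's own composition was predicted to give under 0.25. What gives rise to the trend stays open, since GC bias in each library cannot be measured without values per library, transcript GC content is an imperfect measure of sequenced fragments, and part of the trend may still be technical.

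The excess of rises on the X chromosome was weighed against 3 explanations. After removal of the GC trend the share of X-linked genes that rose was still 2.55 times that elsewhere. Without Mage, Xlr, Rhox, Pramel, Slx and Gm-numbered genes it was 2.10 times. Neither lower GC content nor reads shared within these families is therefore the whole cause. Reads shared among other multicopy genes were not tested. With both the GC trend and these families taken out, 53 of 672 X-linked genes rose, 1.88 times the share elsewhere. A shift of the whole chromosome by 0.1 or more on the log2 scale is argued against by abundant genes. That bound was set after the result was seen. After removal of the GC trend their median lay 0.0302 above that of autosomes (95% bootstrap interval 0.0122 to 0.0484, 314 and 9190 genes). The whole interval is positive, so a smaller shift, as from part of the cells, is not excluded. What sets the rising X-linked genes apart was not tested.

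For the Y-linked rises, loss of the Y chromosome from part of the control cells would raise all abundant Y-linked genes like Kdm5d, whereas Eif2s3y, the most abundant, stood at 0.0568 (interval -0.10 to 0.21, and -0.07 after removal of the GC trend), with upper bounds of 0.30 for Ddx3y and 0.35 for Uty, against a lower bound of 2.03 for Kdm5d. Reads of X-linked partners counted for the Y copies are argued against by Kdm5c, Zfx, Usp9x and Uba1, of which none passed and whose largest upper bound was 0.288. What else raises these Y-linked genes was not tested.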
